A study of Homo sapiens with 2 samples.

How the data were processed

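Single cells of the CT27 trophoblast stem cell line were measured with 10x Genomics 3′ gene expression libraries, per the labels' protocols, as 1 control and 1 PRMT1 knockdown library. The groups were taken from the sample titles. The deposited matrices hold whole UMI counts per gene and barcode. They were made with Cell Ranger 7.2.0, per the file headers. The submitters' processing notes name Cell Ranger 7.2.0, Seurat 5 and the build GRCh38. The annotation release and the treatment of intronic reads are not given in the sources used here. No knockdown method, culture batch or sequencing date was taken into account.

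Both matrices list the same 38606 features, and symbols and identifiers were taken from them. Coordinates, gene spans and chromosomes came from GENCODE 29 (GRCh38), matched on gene identifier, and 98.9% of genes with a mean of at least 10 CPM were matched. XIST, TSIX and Y-linked genes (101 features) were left out of the clustering and of all tables. Barcodes with at least 1000 genes and under 15% mitochondrial UMIs were kept. In the control library 1449 barcodes had too few genes and 90 too high a mitochondrial share, and in the knockdown library 410 and 45, some of them both. The median mitochondrial share of the kept cells was 4.80% in the control and 2.10% in the knockdown library. Scrublet (scanpy 1.11.5) marked 0 cells in either library, under the 0.5% required beforehand for its use, so doublets were kept.

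Counts were summed over the kept cells of each library (129560158 UMIs in the control and 138630816 in the knockdown library) and divided by the total to give CPM. Log2 ratios are knockdown over control on CPM plus a pseudocount of 1, which understates the ratio of low genes. The counts of 2-fold genes went by size alone, at 2-fold or more with a mean CPM of at least 10. List members are called higher or lower by the sign of their log2 ratio, whatever its size. The 1.5-fold class was set after the values were seen. Poisson intervals of counts and Clopper-Pearson intervals of shares, both at 95%, cover counting error only. Cells are not replicates, so with 1 library per group no p-value, standard error or count of significant genes was computed.

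Gene lists (33) were fixed before the data were examined, and members with a mean of at least 5 CPM were used. Antisense and divergent transcripts caught by a family name were left out. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on 20 bins of mean CPM, as a description of these 2 libraries, and its counting interval came from 200 Poisson draws. The immune and erythroid lists had no member at 5 CPM. Named genes were also fixed by rule: the 15 highest and 15 lowest log2 ratios at a mean CPM of at least 20 with one direction under CPM, TMM and median-of-ratios scaling and after thinning, without mitochondrial, ribosomal protein and clone-named genes; the PRMT genes; and up to 4 members of each list with the largest absolute ratio. Other list members were named after their values were seen.

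For clusters, counts per cell were scaled to 10000, log-transformed and reduced to 2000 variable genes, leaving out all cell type markers and mitochondrial genes. Both libraries were clustered together without batch correction on 30 principal components and 20 neighbours, with Leiden (leidenalg 0.10.2) at resolution 0.8. This gave 11 clusters. A cluster was named only with at least 3 class markers at 2-fold or more and 2 of them among its 10 leading genes, a rule set after the clusters were seen. Only the syncytiotrophoblast-like cluster met it. The cluster with TP63 at 2-fold or more over all cells is called TP63-high and is not a named type. Most other clusters came largely from 1 library (cluster 1 held 5349 control and 276 knockdown cells, cluster 3 held 676 and 3496), so they may be the library and not a cell state, and their sizes are given only to describe them. Ratios within clusters used the 6 clusters with at least 100 cells of each library. To compare shares of cells with a UMI, each cell was thinned once to 5000 UMIs, which left out 9247 control and 1533 knockdown cells below that depth.

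Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without mitochondrial and ribosomal protein genes, other cell filters, equal weights for cells, thinning, other pseudocounts and minimum levels, and other cluster settings. Windows of UMIs per cell, cells between the quartiles of UMIs in each library, and clustering without PRMT1 or without the leading genes of the TP63-high cluster were added after the data were seen. The calculations were tested on simulated data: in 1 simulated knockdown-over-control comparison of 8726 genes with counting noise only, 100% of 100 genes changed 3-fold, drawn from genes with a mean of at least 20 CPM, were called, and 0 of 100 genes changed 1.5-fold and 0 unchanged genes were called. Of 200 random unchanged lists, 4.5% fell outside the middle 95% of their random lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3, and figures matplotlib 3.10.9.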

Results

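The data were 2 single-cell RNA libraries of CT27, a human trophoblast stem cell line from placenta. Trophoblast stem cells are the progenitors of the epithelium that covers the placental villi. One library came from control cells and the other from cells in which PRMT1 was knocked down. PRMT1 encodes a protein arginine methyltransferase that places asymmetric dimethylarginine on histones and RNA-binding proteins. The comparison asked which transcripts and cell states of the stem cell culture differ when PRMT1 is depleted. The control library held 20338 barcodes and 131419766 unique molecular identifiers (UMIs), and the knockdown library held 10023 barcodes and 139096009 UMIs. After filtering, 18862 control cells with a median of 5104 UMIs and 9602 knockdown cells with a median of 12480 UMIs remained. Each group had 1 library, so no difference below has a replicate check, and no test between groups was made. The intervals cover counting error only. "Higher" and "lower" describe these 2 libraries.

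PRMT1 was lower in the library labelled knockdown. It had 142 CPM (UMIs of the gene over the library total, in the usual CPM scaling; 95% Poisson interval 140.1 to 144) in the control library and 38.9 CPM (37.8 to 39.9) in the knockdown library, a log2 ratio of -1.84. PRMT1 (ENSG00000126457) lies on the plus strand of chromosome 19 from 49675786 to 49689029 (GRCh38). After each cell was thinned to 5000 UMIs, 48.7% of 9615 control cells (95% Clopper-Pearson interval 47.7% to 49.7%) and 18.0% of 8069 knockdown cells (17.2% to 18.9%) held a PRMT1 UMI. Without thinning these shares were 54.5% and 37.4%. PRMT1 is used by most cell types, so no class of cells here gives a background share for it. The gene was lower in each of the 6 clusters that held at least 100 cells of both libraries, from 2.66-fold in cluster 4 to 4.21-fold in cluster 7. Among the other arginine methyltransferases, CARM1 (64.1 and 50.8 CPM in control and knockdown), PRMT7 (18.4 and 14.7 CPM), PRMT3 (26.7 and 22.4 CPM) and PRMT9 (11.8 and 9.11 CPM) were somewhat lower. CARM1 and PRMT7 were lower in all 6 clusters, PRMT9 in 5 and PRMT3 in 4. The list of 8 measured family members had a median log2 ratio of -0.27 (percentile 0.85 of 10000 random lists), a rank that counts PRMT1 itself. Within clusters that median ran from -0.40 to -0.01. PRMT2, PRMT5 and PRMT6 had log2 ratios of 0.07, -0.02 and -0.09, of which that of PRMT2 turned negative with mitochondrial and ribosomal protein genes left out of the totals and that of PRMT5 turned positive with TMM or median-of-ratios scaling. PRMT8 was near the detection limit, with 5 and 7 UMIs.

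**Figure D1:**
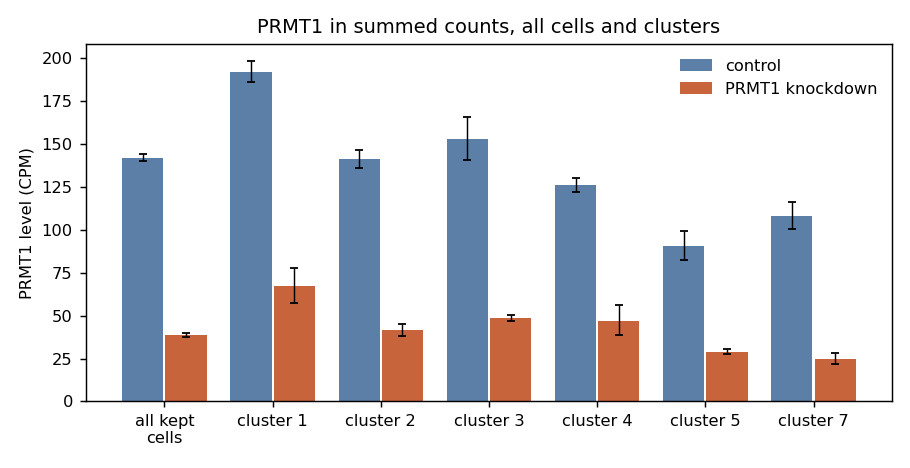
PRMT1 level in CPM (vertical axis) over all kept cells and in the 6 clusters with at least 100 cells of each library. Bars are summed-count values of the control and knockdown libraries, and error bars are 95% Poisson intervals. The knockdown bar lies below the control bar in each pair, at 38.9 against 142 CPM over all kept cells.

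IGFL2, SUN3, NECTIN4 and KRT17 stood highest in the knockdown library. IGFL2, a member of the insulin growth factor-like family on chromosome 19 (46143106 to 46161299, GRCh38), had the largest ratio among the named genes, with 23.1 CPM in the control and 173.5 CPM in the knockdown library. The adhesion molecule NECTIN4 had 8.06 and 36.8 CPM, the keratin KRT17 had 21.6 and 87.6 CPM, and the actin crosslinker FLNC had 14.2 and 55.3 CPM. SUN3, a nuclear envelope protein, had 24.2 and 107 CPM. The cancer-testis gene MAGEA4 had 33.0 and 120.4 CPM, and LY6K had 11.2 and 41.6 CPM. CST6, CAMK2N1, PINCR, IL32, SPARC, IER5 and APOE completed the upper group, with log2 ratios from 1.46 for APOE to 1.75 for CST6. IGFL2-AS1, annotated on the opposite strand of chromosome 19 from 46189166 to 46203083, outside the span of IGFL2, had a log2 ratio of 1.79. MAGEA4 has relatives of similar sequence, and whether reads were shared with them was not tested.

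At the lower end, PRMT1 had the smallest ratio of the named genes. Apart from mitochondrially encoded genes, it was followed by CCKBR, a receptor for gastrin and cholecystokinin on chromosome 11 (6259736 to 6272127, GRCh38), at 55.1 CPM in the control and 18.0 CPM in the knockdown library. C1orf56 had 90.3 and 31.2 CPM, MYL11 had 50.7 and 17.5 CPM, and the xylosyltransferase XYLT1 had 56.6 and 19.9 CPM. The coatomer subunit COPZ1 had 99.6 and 40.1 CPM, the cell adhesion gene CLMP had 196.7 and 80.5 CPM, and the receptor phosphatase PTPRK had 49.6 and 20.2 CPM. ISM2, SORBS2, LINC00668, CCDC141, MED12L, LRRC75A and ERVMER34-1 were also among the 15 lowest. Of these 30 highest and lowest genes, 28 had the same direction in all 6 clusters compared. The exceptions were MED12L, higher in 2 clusters, and LINC00668, higher in 1 cluster. Some ratios were much smaller inside clusters 3 and 5, which held 36.4% and 32.5% of knockdown cells. There CCKBR had log2 ratios of -0.09 and -0.06, MYL11 of -0.31 and -0.32, and CAMK2N1 of 0.49 and 0.19. Knockdown cells made up 83.8% and 82.8% of clusters 3 and 5. Some ratios were also smaller inside clusters 1 and 4, of which knockdown cells made up 4.91% and 3.51%. There CCKBR had log2 ratios of -0.60 and -0.30, XYLT1 of -0.22 and -0.32, and ERVMER34-1 of -0.44 and -0.15. Others were not smaller there, such as C1orf56 at -1.78 and -1.95. The clusters were formed from the same counts, so a smaller ratio inside a cluster may come from the grouping itself.

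**Figure D2:**
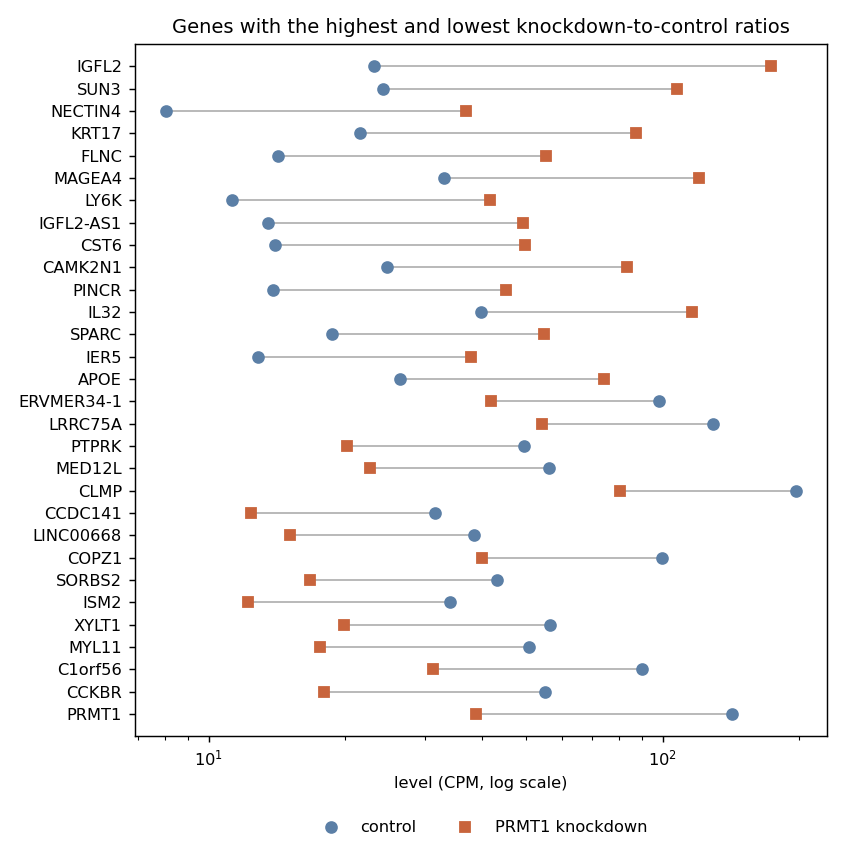
Level in CPM on a log axis of the 15 genes with the highest and the 15 with the lowest knockdown-to-control ratio among genes of mean CPM 20 or more. Circles are the control library and squares the knockdown library, each a sum over kept cells. IGFL2, at the top, had 23.1 and 173.5 CPM, and PRMT1, at the bottom, had 142 and 38.9 CPM.

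Across the 8736 genes with a mean of at least 10 CPM, 93 were at least 2-fold higher and 52 at least 2-fold lower in the knockdown library. The median log2 ratio of all these genes was 0.02, and 93.0% lay within 1.5-fold. Of the 52 lower genes, 8 were mitochondrially encoded. Of the 50 lower genes found in the annotation, 24 were in the fifth of genes with the longest spans, where the median log2 ratio of all genes was -0.13, against 0.10 in the fifth with the shortest spans. The random lists that rank each gene list were matched on expression and not on gene span. The ranks of the lists are therefore not corrected for this trend. With mitochondrial and ribosomal protein genes left out of the totals, the counts were 95 higher and 81 lower, so that the higher genes made up 54.0% of both, against 64.1% with all genes in the totals.

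Markers of the trophoblast stem state were mostly lower in the knockdown library. Of the 14 measured members of that list, 13 were lower and 1 was higher, with a median log2 ratio of -0.43 (counting interval -0.49 to -0.41) that lay below all 10000 random lists of matched expression. PEG10, an imprinted gene derived from a retrotransposon (chromosome 7, 94656325 to 94669695, GRCh38), had 458 CPM in the control and 215 CPM in the knockdown library. TP63, a transcription factor of epithelial progenitors, had 10.5 and 5.21 CPM. Its log2 ratio was -0.89 over all cells and lay between -0.53 and -0.15 inside the 6 clusters. Outside the TP63-high cluster it had at most 5.58 CPM, where the pseudocount understates the ratio. In the TP63-high cluster, which held 19.8% of control and 9.18% of knockdown cells, TP63 had 43.1 and 34.8 CPM. This cluster held 18.7% and 10.6% of cells at 5000 to 10000 UMIs. The order turned to 11.1% and 12.0% at 10000 to 20000 UMIs, and to 2.16% and 7.53% at 20000 UMIs and over. BCAM had 6.98 and 3.18 CPM, and VGLL1, a cofactor of TEAD proteins, had 232 and 143 CPM. With the pseudocount of 1 CPM only PEG10 passed the 2-fold size. The low genes BCAM and TP63 fell short only through it, at log2 ratios of -0.93 and -0.89. TEAD4 (79.2 and 55.4 CPM), LRP2 (501 and 351 CPM) and YAP1 (202 and 159 CPM) differed less. SPINT1 and ITGB4 had log2 ratios of -0.03 and -0.02, and the integrin ITGA6 was the member that was higher, at 124 and 162 CPM. The list's median was below 0 in all 6 clusters, from -0.31 to -0.11, and was -0.29 with clusters weighted equally. At 5000 UMIs per cell, a PEG10 UMI was found in 73.7% of control and 45.8% of knockdown cells, and a VGLL1 UMI in 65.2% and 48.8%. Without thinning the VGLL1 shares were 65.6% and 73.6%, with control and knockdown cells at their full median depths. No background share was available for PEG10 or VGLL1, so these shares include any free RNA.

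Syncytiotrophoblast genes, which mark the fused hormone-producing layer of the placenta, leaned the other way. Of 26 measured members, 19 were higher and 7 lower in the knockdown library, with a median log2 ratio of 0.30 (counting interval 0.27 to 0.33) above all 10000 random lists. The median was 0.56 with each cell weighted equally and 0.48 among cells between the quartiles of UMIs. With the pseudocount of 1 CPM, 5 of these members were 2-fold or more higher and 1 was 2-fold lower. The aromatase gene CYP19A1 had 59.8 and 125 CPM, and KISS1 had 13.9 and 28.7 CPM. The pregnancy-specific glycoproteins PSG9 (log2 ratio 1.86), PSG6 (4.60 and 14.5 CPM), PSG2 (18.2 and 46.1 CPM) and PSG5 (21.1 and 52.4 CPM) were 2-fold or more higher, but these genes are close copies of one another and their separate values are uncertain. PSG2, PSG5, PSG6, PSG9 and KISS1 were also 2-fold or more over other cells in cluster 5, an unnamed cluster that held 3.43% of control and 32.5% of knockdown cells. PSG9 and PSG6 were higher in all 6 clusters compared, PSG2 in 5, and PSG5 in 3 and lower in the other 3. The retroviral envelope gene ERVMER34-1 was the member that was 2-fold lower, at 98.2 and 41.9 CPM. At 5000 UMIs per cell, a CYP19A1 UMI was present in 14.7% of control cells (14.0% to 15.4%) and 22.8% of knockdown cells (21.8% to 23.7%), against 6.72% and 8.10% in the TP63-high cluster taken as background. Without thinning the shares were 15.5% and 37.0%. Other members had a lower share in the knockdown library at 5000 UMIs, among them CGA (34.7% and 26.1%), CGB3 (13.0% and 8.24%), ERVW-1 (20.3% and 13.0%), GCM1 (4.20% and 2.80%) and HOPX (4.77% and 3.59%). Without thinning CGA, CGB3 and ERVW-1 had the higher share in the knockdown library. No background share is given here for CGB3, ERVW-1, GCM1 or HOPX, so theirs include any free RNA. For CGA, the shares in the clusters outside the syncytiotrophoblast-like and TP63-high ones (31.7% and 21.3%) were near those in the TP63-high cluster (28.8% and 21.7%), so a CGA UMI in those cells was read as background.

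One cluster was syncytiotrophoblast-like, with CGA, CGB3, LGALS16, HOPX, INSL4 and LGALS13 among its 10 leading genes and 32 markers of that class at 2-fold or more over other cells. It held 4.23% of control cells (3.94% to 4.52%) and 6.86% of knockdown cells (6.37% to 7.39%). This order did not hold throughout. With at least 2000 genes per cell and under 10% mitochondrial UMIs the shares were 4.91% and 4.42%, and among cells of 10000 to 20000 UMIs they were 6.41% and 5.22%. Inside the cluster, 29 of 38 measured markers were higher in the knockdown library and 9 were lower, with a median log2 ratio of 0.43. CYP19A1 had 613 CPM (595 to 632) in control and 1037 CPM (1016 to 1059) in knockdown cells of the cluster. The steroid enzymes HSD3B1 (83.4 and 149.8 CPM) and CYP11A1 (179 and 286 CPM) and the fusogen genes ERVFRD-1 (38.6 and 66.6 CPM) and ERVW-1 (248 and 364 CPM) were higher as well. CGA was nearly level, at 23302 and 24495 CPM. The chorionic gonadotropin beta genes were lower, with CGB3 at 3594 and 2621 CPM and CGB7 at 80.8 and 27.0 CPM, although reads may be split among these near-identical copies. KISS1, higher over all cells, was lower in this cluster, at 27.5 and 20.8 CPM. Genes named only for this cluster were chosen after their values were seen.

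**Figure D3:**
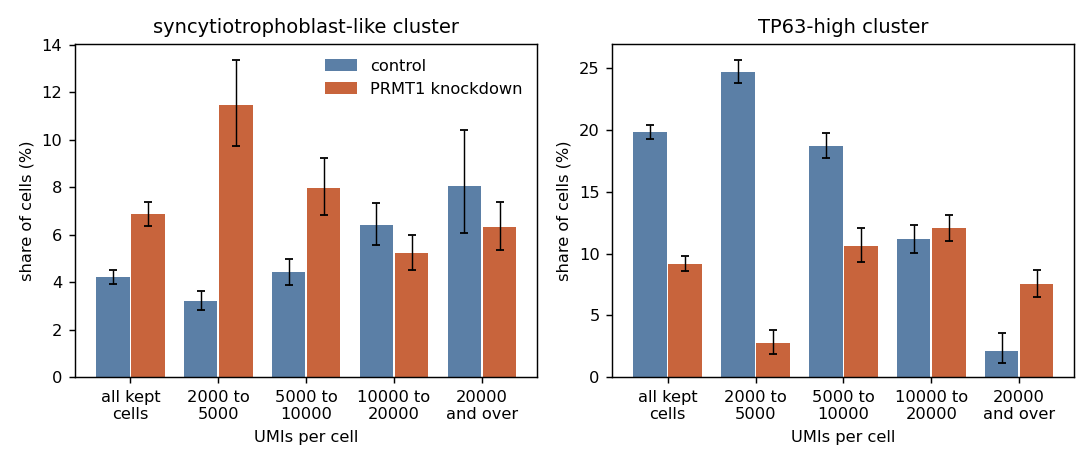
Share of cells (%) in the syncytiotrophoblast-like cluster (left) and in the TP63-high cluster (right), over all kept cells and in windows of UMIs per cell. Bars are the control and knockdown libraries with 95% Clopper-Pearson intervals. For the syncytiotrophoblast-like cluster the order turns from 4.42% and 7.97% at 5000 to 10000 UMIs to 6.41% and 5.22% at 10000 to 20000 UMIs.

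Extravillous trophoblast genes, which mark the invasive lineage, went both ways. Of 12 measured members 7 were higher and 5 lower, and the median log2 ratio of 0.15 was at percentile 90.0 of the random lists. It ranged from 0.077 with mitochondrial and ribosomal protein genes left out of the totals to 0.35 among cells between the quartiles of UMIs. CSF1R (1.97 and 8.87 CPM), PLAC8 (23.1 and 53.5 CPM) and SERPINE2 (46.6 and 95.5 CPM) were 2-fold or more higher over all cells. CSF1R and PLAC8 were higher in all 6 clusters, while SERPINE2 had log2 ratios from 0.11 to 0.18 in 4 clusters, 0.79 in cluster 7 and -0.29 in cluster 4. The integrin ITGA1 was 2-fold lower, at 14.97 and 5.21 CPM, with log2 ratios from -0.98 to -0.28 inside clusters, and the transcription factors ASCL2 (27.7 and 14.9 CPM) and TCF7L2 (262 and 150 CPM) were also lower. All 6 measured genes of the trophoblast cell column list were higher over all cells, including S100P (149 and 272 CPM) and NOTCH1 (6.38 and 12.2 CPM), with a median of 0.69 above all random lists. Within clusters that median was above 0 in 4 and below 0 in 2. Markers of other cell types were few. The amnion list (3 members, median 0.45 at the upper edge of its random range, HEY1 at 3.75 and 7.75 CPM), the stromal list (3 members, 0.42, percentile 97.6, COL1A2 at 85.0 and 114 CPM, COL1A1 at a log2 ratio of -0.03) and the endothelial list (2 members, 0.51, EGFL7 at 11.2 and 20.5 CPM) had medians above 0. COL1A2 was a leading gene of the TP63-high cluster, at 356 and 793 CPM there. COL1A1 was higher in all 6 clusters, with log2 ratios from 0.28 to 0.50. The endothelial median was inside its random range (-0.44 to 0.65), and was -0.03 with all members that had a count. Of the pluripotency list only LIN28A was measured, at 27.8 and 21.4 CPM. No immune or erythroid marker reached 5 CPM.

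Cell cycle genes differed little over all cells. The S phase list had a median log2 ratio of -0.06 over 43 members (percentile 6.94), with CDCA7, a replication-associated gene, lowest at 63.9 and 41.5 CPM. Within clusters that median was below 0 in all 6, from -0.51 in cluster 1 to -0.02 in cluster 5, while among cells of 10000 to 20000 UMIs it was 0.13. The G2M phase list had a median of 0.11 over 53 members, at the upper edge of the middle 95% of random lists (-0.07 to 0.11), with 36 higher and 17 lower and none past 1.5-fold. Within clusters its median was below 0 in 4, lowest at -0.51 in cluster 1, and above 0 in 2, at 0.02 in cluster 3 and 0.04 in cluster 5. With clusters weighted equally it was -0.11.

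Targets of p53 and of NF-kB leaned higher in the knockdown library, mostly by less than 2-fold. Of 25 measured p53 targets, 23 were higher and 2 lower, with a median log2 ratio of 0.41 above all random lists and above 0 in all 6 clusters. Only PLK2 passed the 2-fold size, and 16 of the 25 lay within 1.5-fold. PLK2 (22.7 and 55.7 CPM), PLK3 (26.8 and 52.0 CPM), the proapoptotic gene BBC3 (9.75 and 19.1 CPM) and BTG2 (14.0 and 26.0 CPM) had the largest differences. CDKN1A, the cell cycle inhibitor on this list, had 110.3 and 132 CPM, a direction that turned among cells of 10000 to 20000 UMIs (log2 ratio -0.15) and in 3 of the 6 clusters (lowest -0.41 in cluster 5). Of 9 measured NF-kB targets 8 were higher, 1 of them (IL32) by 2-fold, with a median of 0.59 above all random lists. The list was led by IL32 (39.9 and 116 CPM), RELB (7.66 and 15.2 CPM) and NFKB2 (3.33 and 7.07 CPM). The low gene NFKB2 fell short of 2-fold only through the pseudocount of 1 CPM. The cluster medians of this list ran from 0.04 in cluster 4 to 0.82 in cluster 2. Genes of the unfolded protein and integrated stress response had a median of 0.38 over 21 members, also above all random lists, with 18 higher, 2 of them (DDIT4 and CHAC1) by 2-fold. DDIT4 (5.23 and 17.1 CPM), CHAC1 (5.40 and 14.0 CPM) and HERPUD1 (68.6 and 130.1 CPM) had the largest ratios among them, and cluster medians ran from 0.07 to 0.63. The immediate early and heat shock list had a median of 0.35 (percentile 99.97, 15 higher and 3 lower of 18, 1 higher by 2-fold with the pseudocount), with cluster medians from 0.05 to 0.23 in 5 clusters and 0.57 in cluster 7. In it KLF4 had 4.60 and 10.3 CPM and EGR1 was lower at a log2 ratio of -0.84.

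**Figure D4:**
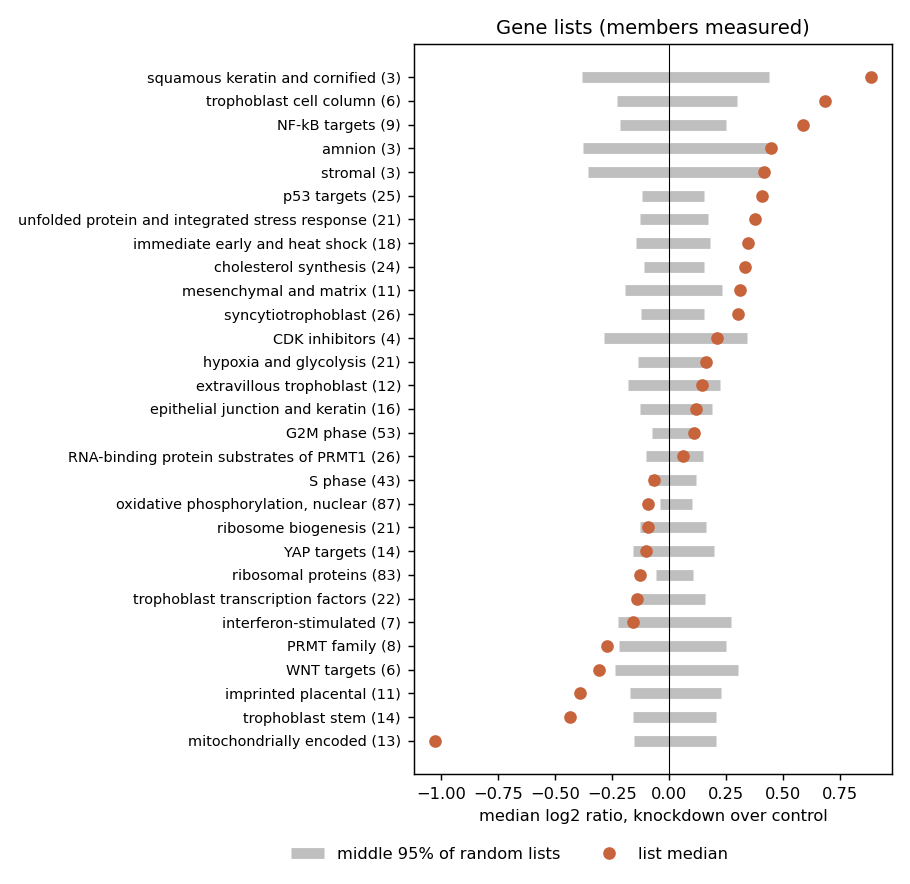
Median log2 ratio, knockdown over control, of each gene list with at least 3 measured members (points; number of members in brackets), beside the range of the middle 95% of random lists matched on expression (grey bars). The mitochondrially encoded list lies lowest at -1.02 and the trophoblast stem list next at -0.43.

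The 13 genes encoded by the mitochondrial genome were all lower in the knockdown library, with a median log2 ratio of -1.02 below all random lists. MT-CO3 had 5728 and 1830 CPM, MT-ATP6 had 6962 and 2384 CPM, MT-ND3 had 4337 and 1714 CPM and MT-ND6 had 116 and 38.7 CPM. The difference was uneven, with log2 ratios of -0.37 for MT-ND2 and -0.04 for MT-ND4L. Together these genes took 42857 CPM in the control and 19334.5 CPM in the knockdown library. The median of the list lay between -1.10 and -0.82 in the 6 clusters. The nuclear genes of oxidative phosphorylation had a median of -0.09 over 87 members (percentile 0.04), with 26 higher and 61 lower, of which SDHD (51.3 and 32.9 CPM) was the lowest and COX7B2 (8.21 and 25.4 CPM) the highest. Within clusters that median was above 0 in 4 and below 0 in 2.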

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

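The windows of UMIs per cell, the cells between the quartiles of UMIs in each library, and the clusterings without PRMT1 or without the leading genes of the TP63-high cluster were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Scrublet marked 0 cells, so there were no calls to leave out, and whether doublets affect these results was not tested. PRMT1 was lower under each alternative, with a log2 ratio of -1.82 with TMM, -1.79 with median-of-ratios scaling, -1.93 without mitochondrial and ribosomal protein genes in the totals, -1.78 with the stricter cell filter, -1.70 after thinning, -1.75 with a pseudocount of 5, -1.51 among cells of 10000 to 20000 UMIs and -1.77 between the quartiles. Among 2-fold higher genes, 204 were found at a minimum mean CPM of 1 and 26 at 50, and among lower genes 79 and 15, as fewer or more genes are counted, and 81 lower genes with mitochondrial and ribosomal protein genes out of the totals. All 93 higher and 52 lower genes kept their direction under the scaling and cell alternatives. Of these, 77 and 41 were still 2-fold among cells of 10000 to 20000 UMIs. Within clusters fewer kept it, with 68 of the 93 and 47 of the 52 having that direction in all 6 clusters compared. The stem list's median was -0.38 with median-of-ratios scaling, -0.51 with the reduced totals and -0.29 with clusters weighted equally. The syncytiotrophoblast median was 0.36 and 0.23 under the same scalings, 0.27 with the stricter filter, 0.56 with equal weight per cell, 0.24 at 10000 to 20000 UMIs, 0.48 between the quartiles and 0.20 over clusters. The extravillous median was 0.077 with reduced totals, 0.22 with equal weights, 0.24 after thinning, 0.23 at 10000 to 20000 UMIs and 0.35 between the quartiles. The S phase median was -0.038 with TMM, -0.0050 with median-of-ratios scaling, -0.14 with reduced totals, -0.043 with the stricter filter, -0.14 with equal weights, 0.13 at 10000 to 20000 UMIs, -0.12 between the quartiles and -0.19 over clusters. The G2M median was 0.14 with TMM, 0.17 with median-of-ratios scaling, 0.033 with reduced totals, 0.067 with equal weights and 0.029 after thinning, and it turned to -0.054 between the quartiles and -0.11 over clusters. For these lists the cause was not tested.

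The difference in the share of syncytiotrophoblast-like cells, 2.64 points in the main setting, was 0.51 at resolution 1.2, 0.25 with cell type markers kept, -0.49 with the stricter filter, 0.31 without the leading genes of the TP63-high cluster, 3.56 at 5000 to 10000 UMIs, -1.19 at 10000 to 20000 UMIs and 1.80 between the quartiles. For the TP63-high cluster it was -10.7 points in the main setting, -11.6 without cell cycle lists, -7.22 with components centred per library, -5.86 with the stricter filter, -9.09 without its leading genes, -8.09 at 5000 to 10000 UMIs and 0.89 at 10000 to 20000 UMIs. For these shares the cause was not tested beyond depth. The share of cells with a PRMT1 UMI differed by -30.6 points at 5000 UMIs, -23.2 at 3000 UMIs and -17.0 without thinning. Without thinning, the knockdown library had the higher share for TEAD4 (11.3 points), LRP2 (2.30), EGFR (12.2), FZD5 (8.19), ITGB4 (18.1), VGLL1 (8.04), YAP1 (12.7), CGA (10.6), CGB3 (1.202), ERVW-1 (1.89), DEPP1 (3.11), ASCL2 (1.13) and TCF7L2 (4.69), while after thinning to 5000 UMIs, which also left out the shallower cells, each was lower. Which of these choices turned the direction was not tested. Of 144 named genes 137 kept their direction under each alternative run for genes, as did 21 of the 26 other lists under theirs. For the genes this was partly fixed by their selection. Those with the highest and lowest ratios had to keep their direction under TMM and median-of-ratios scaling and after thinning. Members named by rule from lists were picked for large ratios. The runs for genes did not include clusters weighted equally, unlike those for lists. CDKN1C, at a log2 ratio of -0.42 over all cells, was higher in each of the 6 clusters compared.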

Other observations

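The test of length bias as the whole cause and that of nuclear RNA were chosen after their results had been seen. In the epithelial junction and keratin list KRT18 (4103 and 8038 CPM in the control and knockdown library), KRT8 (1548 and 2838 CPM) and KRT7 (473 and 776 CPM) were higher and KRT23 (35.1 and 23.0 CPM) was lower, with a list median of 0.12 inside the random range. The squamous list had 3 measured members, all higher (median 0.89 over all cells and 0.08 to 0.94 in clusters). Cholesterol synthesis genes had a median log2 ratio of 0.34, above all 10000 random lists, with 21 of 24 members higher, none of them by 2-fold and 19 of the 24 within 1.5-fold. Among them were MVD (62.2 and 107.9 CPM), HMGCS1 (271 and 453 CPM) and HMGCR (73.1 and 115 CPM). The mesenchymal and matrix list had a median of 0.31 (percentile 99.8), with MMP14 at 17.4 and 31.9 CPM, but its median was below 0 in 2 of 6 clusters. Hypoxia and glycolysis genes had a median of 0.16 (percentile 97.3), inside the random range, with ADM at 25.2 and 41.0 CPM.

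Imprinted placental genes were mostly lower over all cells, with a median of -0.39 (percentile 0.01) and 9 of 11 members lower, including PEG3 (46.3 and 21.5 CPM) and IGF2 (74.1 and 37.3 CPM). Inside clusters the median was smaller, from -0.38 to -0.03 with a mean of -0.22. IGF2 was lower in all 6 clusters but unevenly. It had log2 ratios of -0.93 in cluster 5 and -0.83 in cluster 3, against -0.03 in cluster 7 and -0.09 in cluster 4. CDKN1C, also on the CDK inhibitor list, was lower over all cells (278 and 207 CPM). It was higher in all 6 clusters, with log2 ratios from 0.19 to 1.24. PEG10 is also a member of the stem list. WNT targets had a median of -0.31 (percentile 0.86, 5 of 6 lower, ZNRF3 at 139 and 73.8 CPM), trophoblast transcription factors -0.14 (percentile 1.64), with ID2 at 8.92 and 4.40 CPM and ELF3 higher at 33.8 and 55.6 CPM, and ribosomal proteins -0.13 (percentile 0.01). The medians of the transcription factor and ribosomal protein lists were each above 0 in 3 clusters and below 0 in 3. Inside the random range, unlike those above, were the medians of the interferon-stimulated list (-0.16, IFI6 at 99.7 and 57.7 CPM), YAP targets (-0.10), ribosome biogenesis (-0.09), CDK inhibitors (0.21) and RNA-binding protein substrates of PRMT1 (0.06, HNRNPH1 at 303 and 179.9 CPM). The last of these turned to -0.01 with mitochondrial and ribosomal protein genes out of the totals, and YAP targets to 0.07 with all members that had a count.

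Long genes were lower in the knockdown library. The median log2 ratio fell across span quintiles from 0.10 to -0.13, and the longest minus the shortest was -0.24, as a length bias between the libraries would give. As the whole cause of the lower long genes it is open, since 66.7% (16 of 24) stayed 2-fold lower after subtracting the median of genes of like span. A lower share of nuclear RNA is open too, with -0.15 for NEAT1 against 0.39 for MALAT1. The knockdown itself was not tested, and with 1 library per group it and the library preparation cannot be told apart.

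Mitochondrially encoded genes were lower in the knockdown library. Low-quality control cells are argued against by a median log2 ratio of -0.98 with the stricter filter. Depth per cell is argued against by -0.81 among cells of 10000 to 20000 UMIs. A different mix of cell states, so far as the clusters mark them, is argued against by -0.99 averaged over 6 clusters. The library preparation and the knockdown remain open.

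The knockdown library held fewer TP63-high cells and more syncytiotrophoblast-like cells. Knockdown cells that had kept PRMT1 are argued against as the remaining TP63-high cells, since PRMT1 had a log2 ratio of -1.75 inside that cluster. Depth per cell may account for both shares, as the differences were 0.89 and -1.19 points among cells of 10000 to 20000 UMIs, which met the bounds set beforehand for that explanation. It was left undecided by a condition added after the values were seen, because at 5000 to 10000 UMIs the differences were -8.09 and 3.56 points, at 2000 to 5000 UMIs -21.9 and 8.24 points, and at 20000 UMIs and over 5.37 (3.59 to 6.89) and -1.73 points (-4.29 to 0.52). The knockdown as a cause was not tested apart from the library.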
